A study of Mus musculus with 97 samples.

How the data were processed

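Gene expression was measured with the NanoString GeoMx Digital Spatial Profiler and the mouse Whole Transcriptome Atlas, a panel of probes whose tags are cut loose by ultraviolet light from chosen regions of a tissue section and then sequenced. The 97 libraries came from 49 captured regions of cortex and 48 of hippocampus, in brain sections of 8 µm from older mice that carry human APOE3 or APOE4. Per the labels' protocols, mice received vehicle, DD (doxorubicin at 3 mg/kg and docetaxel at 10 mg/kg per week) or DC (doxorubicin at 3 mg/kg and cyclophosphamide at 40 mg/kg per week). Injections into the peritoneum were given 2 times per week for 2 weeks. Sequencing was on an Illumina NovaSeq instrument per the labels, and the submitters' processing notes name the mm10 genome build. The counting software, its version and the filters are not given in the sources used here.

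The deposited values are expected counts per probe target, not scaled to depth, in a table of 19963 rows, of which 19962 are genes and 1 is the combined negative probe. The values are whole numbers in all but 4 rows, the negative probe and 3 genes. The lowest value was 1 in 94 of the 97 libraries. A comparison of probe rates in 57 libraries fitted a count of 0 written as 1 better than 1 added to every count in 55 of them. Values were rounded to whole numbers before modelling.

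Libraries were grouped by genotype, treatment and region as the labels give them, into 12 groups of 8 libraries, with 9 in APOE3 DD cortex. The labels do not tie captured regions to animals, so the region was the unit, and p-values over regions are too small where regions share an animal. All APOE4 libraries carried the name of 1 collection plate and all APOE3 libraries that of the other, so 0 genotypes were found on both plates. Libraries that follow each other on the plate and share a group were treated as a run of wells; there were 49 runs, 48 of them with 2 libraries. The order of runs was not used to pair groups: the median correlation of runs of the same order across groups was 0.0651 in cortex and 0.124 in hippocampus, with lowest values of -0.205 and -0.300, against medians of -0.0178 and -0.0614 for runs of other order. No libraries were identical (0 of 97), and all 97 were used in the fits.

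For each region, edgeR 4.0.16 in R 4.3.3 was fitted to all 6 groups with TMM scaling, the filterByExpr filter (minimum count 10), the quasi-likelihood F test and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. This left 57 genes in cortex and 38 in hippocampus. Log2 CPM, computed with a prior count of 2, were scaled to the summed counts of the tested genes. The 23 contrasts were DD and DC against vehicle, APOE4 against APOE3, their interaction, DD against DC, and hippocampus against cortex in vehicle libraries; the last was fitted to the 4 vehicle groups. Errors of log2 fold changes are standard errors (SE) derived from the F statistic. Negative probe values and tested-gene counts were compared with two-sided exact permutation tests over libraries, with Benjamini-Hochberg adjustment over the contrasts, and also over 4 runs of wells against 4. The tests over runs left out APOE3 DD cortex 3, the only library of its run.

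The 38 gene lists were tested with camera (limma 3.58.1) on log2 CPM of all genes, with a preset correlation of 0.01 and with an estimated one. They were homeostatic microglia, disease-associated microglia, complement, cytokines and NF-kB targets, interferon response, antigen presentation, reactive astrocytes, astrocytes, myelin and oligodendrocytes, oligodendrocyte precursors, endothelial cells, mural cells, fibroblasts and meninges, choroid plexus and blood cells. Neuronal and regional lists were excitatory neurons, inhibitory neurons, cortex, hippocampus, thalamus and striatum markers, dentate neurogenesis and proliferation, immediate early genes, synaptic vesicle and release, glutamate receptors and postsynaptic density, and neurotrophic and neuroprotective factors. The others were oxidative phosphorylation, glycolysis, the TCA cycle, cholesterol and lipid transport, the p53 and DNA damage response, senescence, antioxidant response, heat shock and chaperones, ER stress, glucocorticoid response, tubulins and microtubule proteins, and ribosomal proteins.

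The lists, the contrasts and the rule for naming genes were fixed before the data were examined. Where fewer than 20 genes passed, the rule names all of them. With 20 or more it names up to 10 in each direction with the largest changes among genes at or above the median level, and with none it names the 5 smallest p in each direction. Up to 4 members of each list described, and Apoe, Gfap, Aif1, Cdkn1a, Bdnf and Mbp, are named in any case. Some genes that the rule names are not reported here; counts include them. Coordinates come from the annotation table, in which 57 of the 58 tested symbols were found.

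The alternatives tried were upper-quartile scaling, DESeq2 1.42.0, no low-count filter, counts summed over runs of wells, limma voom with the run as a random block, the order of the run as a fixed block, only the groups of a contrast in the fit (all 12 groups for hippocampus against cortex), and leaving out the runs of each order in turn. Alternatives chosen after seeing the data were subtraction of the negative probe value and a covariate, the log2 ratio of that value to the tested-gene count. Also tried were leaving out the 13 libraries with a negative probe value of 5 or more, and a filter at 5 times the negative probe. The others left out the 7 libraries with 5 or more genes raised in that library alone, also without the low-count filter, or the library APOE4 vehicle hippocampus 3. The fits were tested on simulated data. With 2-fold changes, edgeR called 78.3% of the changed genes in APOE3 cortex, 97.1% in APOE4 cortex, 81.2% in APOE3 hippocampus and 96.7% in APOE4 hippocampus. Simulated libraries were independent, without the correlation within runs that the data hold, so these shares are not the power of the real design. Groupings of the libraries at random (100 per contrast, the real one included) gave the number of genes that chance can produce, and for contrasts of 2 groups within a region, 35 groupings kept each run of wells whole, again without APOE3 DD cortex 3.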

Results

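Gene expression was profiled in captured regions of cortex and hippocampus from older mice carrying human APOE3 or APOE4, after vehicle or 1 of 2 chemotherapy regimens. The study's question was how the APOE allele and combined chemotherapy affect inflammatory, metabolic and neuroprotective genes. Each of the 12 groups of genotype, treatment and region held 8 libraries, except APOE3 DD cortex with 9. Total counts per library ran from 21568 to 1850582, with a median of 44846. The median was 30579 in the 49 APOE3 libraries and 61380 in the 48 APOE4 libraries. These totals hold at least 1 for each gene, the lowest value in the files; over that floor, the medians were 10617 and 41418. The combined negative probe, which has no target in the genome and measures background, had a median value of 1.27 in APOE3 and 2.68 in APOE4 libraries, and a highest value of 93.1. In the median library, 41.7% of genes stood at the lowest value of 1.

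**Figure D1:**
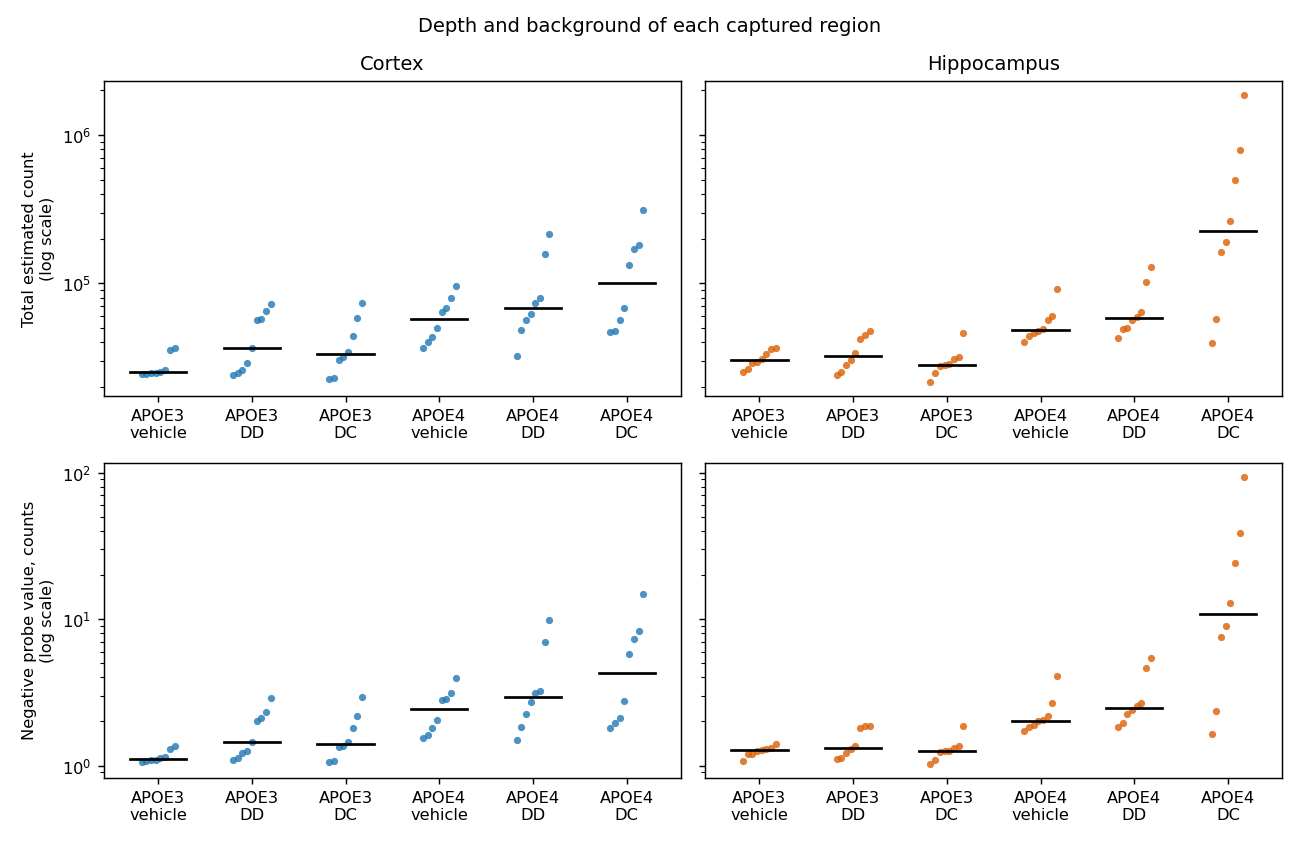
Total count and negative probe value of each library by group, on log axes. Totals ran from 21568 to 1850582, and the highest negative probe value of 93.1 lay in an APOE4 DC hippocampus library.

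Mtch2, a protein of the outer mitochondrial membrane, had the highest probe signal of the tested genes, at a median of 358 times the negative probe in cortex and 644 times in hippocampus. Gm10265 and Gm52523, both predicted genes, followed in cortex at 230 and 131 times (73.1 and 36.3 times in hippocampus). In hippocampus Gm33888 and Gm46840, also predicted genes, followed at 133 and 110 times. Most genes did not rise above background: the median gene lay at 0.936 times the negative probe in cortex and 0.912 times in hippocampus, and 97 and 60 genes exceeded it more than 2-fold. The low-count filter left 57 genes in cortex and 38 in hippocampus, 37 of them in both. These genes held 693 to 13999 counts per library, a median of 6.89% of the total. Of the 664 members of the 38 fixed gene lists, Olig2, a transcription factor of the oligodendrocyte lineage, was the 1 gene tested. Slc17a7, the vesicular glutamate transporter of excitatory neurons, reached 1.9 times the negative probe in cortex, and the glycolytic genes Aldoa and Pkm 2.81 and 2.68 times. No list had a median member above the negative probe; the highest was 0.997 times in cortex and 0.956 times in hippocampus.

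Mtch2 was 3.05-fold higher in vehicle hippocampus than in vehicle cortex (log2 1.61, SE 0.18, edgeR adjusted p = 7.58e-10, above the cortex mean in 16 of 16 hippocampus libraries). Hmga2, a chromatin protein, Xrn1, a cytoplasmic exoribonuclease, Erlin2, a lipid-raft protein of the endoplasmic reticulum, and Ripply2, a transcriptional corepressor of somite formation, were 2.27-, 2.48-, 2.55- and 2.52-fold higher, each in 16 of 16 libraries. The predicted genes Gm33888, Gm34733 and Gm46840 were 2.86-, 2.80- and 2.51-fold higher. Chic2, a palmitoylated membrane protein, was 1.87-fold lower in hippocampus (log2 -0.90, SE 0.14, adjusted p = 8.30e-07, 16 of 16 libraries). Lower values of 1.40- to 1.73-fold were found for Gm40755, Gm52523, Cd99, a surface glycoprotein of leukocyte migration, Gm10265, Tysnd1, a peroxisomal protease, Trir and 1110065P20Rik. Lrr1, the substrate receptor of a cullin ubiquitin ligase, was 1.19-fold lower (log2 -0.25, SE 0.11, adjusted p = 0.0366), in 9 of 16 libraries, and lost its call without APOE4 vehicle hippocampus 3 (log2 -0.22).

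Of the 37 genes tested in this comparison, 28 passed, 14 higher and 14 lower, against 29 by DESeq2. The first principal component over the 58 tested genes held 37.1% of the variance and placed 0 of the 97 libraries on the side of the other region. The labels do not tie the 97 regions to animals, so these p-values, taken over regions, are too small where regions share an animal. The fixed cortex and hippocampus marker genes could not serve as a check, since their members lay at background and put 46 of 97 libraries on the wrong side.

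**Figure D2:**
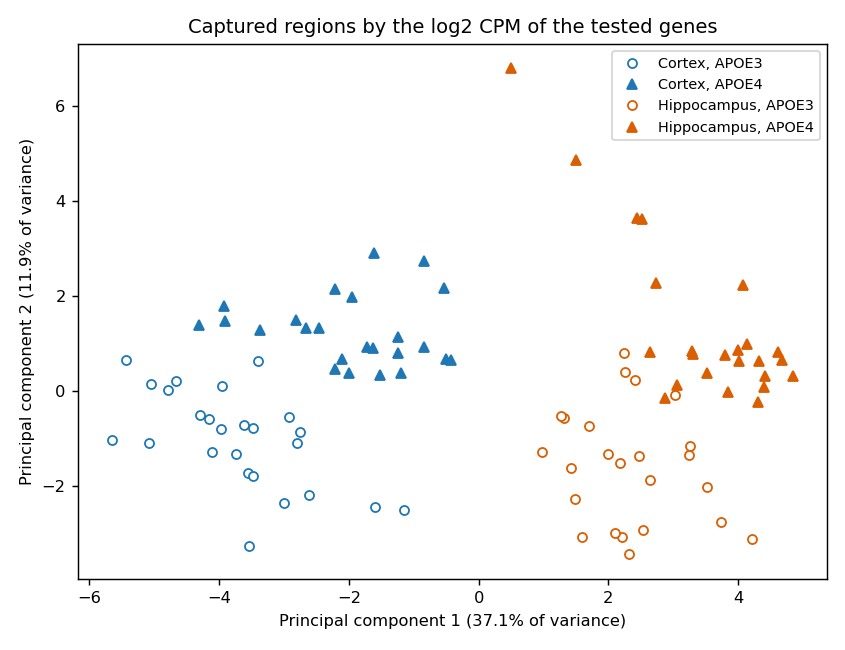
Principal components of the 97 libraries over log2 CPM of the 58 tested genes, with the first component (37.1% of the variance) against the second (11.9%). The 49 cortex and 48 hippocampus libraries separated on the first component with 0 exceptions.

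The treatment comparisons asked which genes differ between regions of DD- or DC-treated mice and those of vehicle-treated mice. In APOE3 cortex, Mtch2 was 1.82-fold lower after DD (log2 -0.87, SE 0.22, edgeR adjusted p = 0.00450, below the vehicle mean in 9 of 9 libraries) and 2.26-fold lower after DC (log2 -1.18, SE 0.23, adjusted p = 0.000137, 8 of 8 libraries). Its share of the tested counts was 34.7% ± 7.08 (SD, n = 8) in vehicle, 22.8% ± 4.28 (SD, n = 9) after DD and 18.8% ± 8.79 (SD, n = 8) after DC. Ripply2 was 1.88-fold lower after DD (log2 -0.91, SE 0.22, adjusted p = 0.00450, 9 of 9 libraries) and 1.96-fold lower after DC (log2 -0.97, SE 0.25, adjusted p = 0.00392, 7 of 8 libraries). After DC, Gm34733, Gm33888 and Cd99 were also lower, by 1.92-, 1.54- and 1.48-fold, each in 8 of 8 libraries (adjusted p = 0.00392, 0.0169 and 0.00530). Elof1, a transcription elongation factor, was 2.51-fold higher after DC (log2 1.33, SE 0.41, adjusted p = 0.0169) and Ptms, the small acidic protein parathymosin, 2.03-fold higher (log2 1.02, SE 0.31, adjusted p = 0.0168), each in 8 of 8 libraries. Over the cortex libraries of both genotypes, Elof1 and Ptms lay at medians of 4.92 and 3.87 times the negative probe. In APOE3 vehicle cortex, the Elof1 counts lay near the lowest value of 1. In mm10, Mtch2 lies on chromosome 2 at 90847090 to 90866810, Ripply2 on chromosome 9 at 87015537 to 87020441 and Elof1 on chromosome 9 at 22112986 to 22117195, all protein-coding.

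In APOE4 cortex, 7 genes passed after DD and 1 after DC. Mtch2 was 1.63-fold lower after DD (log2 -0.71, SE 0.22, adjusted p = 0.0366, 8 of 8 libraries); after DC its log2 fold change was -0.70 (SE 0.22, adjusted p = 0.0639), short of the threshold. Ripply2, Xrn1, Gm46840 and Chic2 were 1.52-, 1.43-, 1.42- and 1.36-fold lower after DD (adjusted p = 0.0490, 0.0490, 0.0366 and 0.0490) in 8, 8, 8 and 7 of 8 libraries. Ctxn1, the neuronal membrane protein cortexin, was higher after both regimens, 1.42-fold with DD (log2 0.51, SE 0.16, adjusted p = 0.0366, 8 of 8 libraries) and 1.49-fold with DC (log2 0.58, SE 0.16, adjusted p = 0.0370, 7 of 8 libraries). Coa5, an assembly factor of cytochrome c oxidase, was 1.35-fold higher after DD (log2 0.43, SE 0.14, adjusted p = 0.0366, 8 of 8 libraries).

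The captured regions are not tied to animals in the labels, so these p-values over regions are too small where regions share an animal. With counts summed over runs of wells, the DD calls of both genotypes and the Ctxn1 call after DC ended (0 calls each), while 5 of the 7 DC calls in APOE3 remained, without Elof1 and Ptms. With the run as a random block, the calls in APOE3 were kept for 2 of 2 genes after DD and 5 of 7 after DC, and those in APOE4 ended. The 7 DD calls in APOE4 also ended under upper-quartile scaling and without the 7 libraries with many genes raised in 1 library alone, and Ctxn1 after DC ended under both as well. The negative probe itself was 1.41-fold higher than in vehicle after DD (two-sided exact permutation p = 0.0198 over libraries, adjusted 0.0397, but 0.114 over runs of wells) and 1.36-fold higher after DC (exact p = 0.0272, adjusted 0.0490, but 0.171 over runs) in APOE3 cortex.

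In APOE3 hippocampus, Mtch2 was 2.16-fold lower after DC (log2 -1.11, SE 0.28, edgeR adjusted p = 0.00439, 8 of 8 libraries). Its share of the tested counts was 58.7% ± 6.20 (SD, n = 8) in vehicle and 40.5% ± 9.32 (SD, n = 8) after DC. Shares here and above are not TMM-scaled, so their ratios differ from the folds. Txlnb, a member of the taxilin family, was 2.45-fold lower (log2 -1.29, SE 0.27, adjusted p = 0.000743, 8 of 8 libraries). After DC it held a small share of a mean of 1048 tested counts per library, so its counts lay near the lowest value of 1. Gm34733 and Ripply2 were 1.68- and 1.56-fold lower (adjusted p = 0.00439 and 0.0324, 8 of 8 libraries each). Cyp2d12, a cytochrome P450, was 3.34-fold higher after DC (log2 1.74, SE 0.50, adjusted p = 0.00977, 8 of 8 libraries), but from mean counts of 1.63 per library in vehicle and 3.00 after DC, next to the lowest value of 1. Fam177a, Gimap4, a GTPase of lymphocytes, and Tmed2, a cargo receptor of the secretory pathway, were 2.02-, 1.94- and 1.68-fold higher (adjusted p = 0.0390, 0.0168 and 0.0265) in 8, 6 and 8 of 8 libraries. After DD, Ripply2 alone passed, 1.82-fold lower (log2 -0.87, SE 0.21, adjusted p = 0.00575, 8 of 8 libraries), a call that ended under upper-quartile scaling.

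In APOE4 hippocampus, 8 genes passed after DC and 2 after DD. Pcbd2, a pterin dehydratase, Etd, Fam177a and the olfactory receptor Olfr655 were 1.84-, 1.77-, 1.60- and 1.57-fold higher after DC (adjusted p = 0.0303, 0.0377, 0.0397 and 0.0377) in 8, 7, 6 and 6 of 8 libraries. Hmga2, Gm46840 and Lrr1 were lower (log2 -0.58, -0.57 and -0.48, SE 0.21, 0.20 and 0.16, adjusted p = 0.0397, 0.0377 and 0.0377) in 8, 6 and 8 of 8 libraries. Tysnd1 was 1.42-fold higher after DD (log2 0.51, SE 0.15, adjusted p = 0.0206, 8 of 8 libraries). Mplkip, a protein linked to trichothiodystrophy, was lower after DD (log2 -2.74, SE 0.53, adjusted p = 0.000131, 8 of 8 libraries) and after DC (log2 -1.91, SE 0.48, adjusted p = 0.00861, 6 of 8 libraries). Both values rest on APOE4 vehicle hippocampus 3, which held 484 Mplkip counts against a median of 6 in the other hippocampus libraries; without it they were -0.44 and 0.40 (adjusted p = 0.385 and 0.229), and Etd also lost its call (log2 0.66).

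These p-values were again taken over regions that the labels do not tie to animals, and are too small where regions share one. The negative probe was 5.16-fold higher after DC than in vehicle in APOE4 hippocampus (two-sided exact permutation p = 0.00466 over libraries, adjusted 0.0163, but 0.114 over runs of wells); without the 13 libraries with a negative probe value of 5 or more, which leaves 2 of the 8 DC libraries there, both of 1 run, 0 of the 8 DC calls in APOE4 hippocampus remained. Fam177a turned to log2 -0.57 (SE 0.40), while Lrr1 went to -0.80 (SE 0.27) and Mplkip to -3.06 (SE 1.04), larger changes with wider errors. The other 5 shrank towards 0: Pcbd2 from log2 0.88 to 0.22, Etd from 0.83 to 0.015, Olfr655 from 0.65 to 0.11, Hmga2 from -0.58 to -0.28 and Gm46840 from -0.57 to -0.091. In APOE3 hippocampus after DC the tested-gene count fell to 1048 ± 384 (SD, n = 8) from 2913 ± 1253 (SD, n = 8). The exact permutation p was 0.00109 over libraries and 0.0286, the smallest possible, over runs. With the covariate, which divides the negative probe by this count, 1 of the 8 calls remained. Summing runs of wells left 6 of the 8 DC calls in APOE3, 1 of 8 in APOE4, and 0 of 1 and 1 of 2 of the DD calls. With the run as a random block, the DC and DD calls in APOE4 hippocampus all ended.

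**Figure D3:**
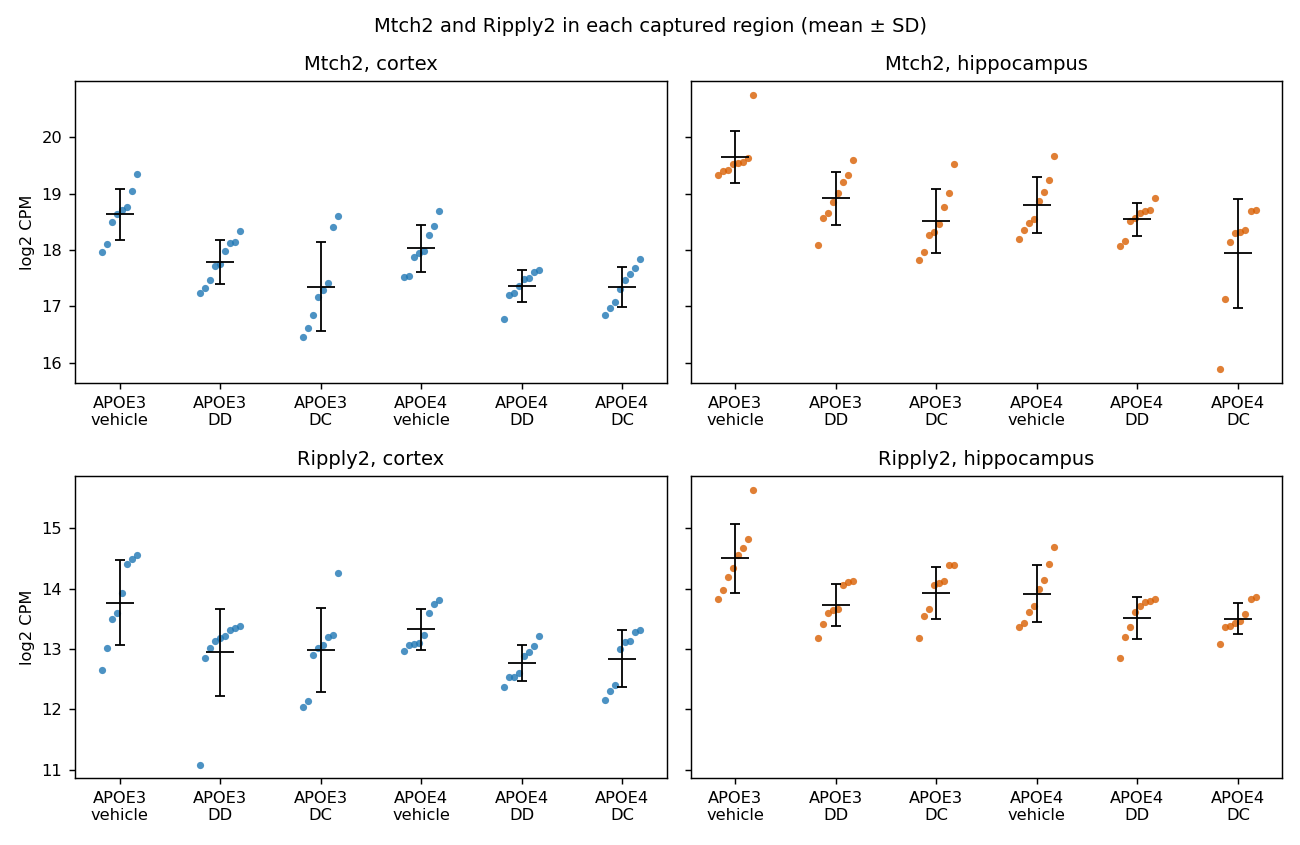
Log2 CPM of Mtch2 and Ripply2 in each library by group and region, with group means and SD bars. Mtch2 was 1.82-fold lower than vehicle after DD and 2.26-fold lower after DC in APOE3 cortex.

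Both regimens contain doxorubicin and share the vehicle libraries. In APOE3 cortex, Mtch2 and Ripply2 were lower after both DD and DC, 2 genes in common where independent lists would share 0.175. With the vehicle libraries split so that each regimen had its own, the overlap was 0 to 2 genes. The 1 gene in common in APOE4 cortex (Ctxn1), APOE3 hippocampus (Ripply2) and APOE4 hippocampus (Mplkip) fell to 0 with split vehicle libraries. The split left each regimen fewer vehicle libraries, so a call could also end through lower power, and the 2 cannot be told apart here.

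Gene lists were tested over all genes, most of them at background. Ribosomal protein genes had lower values after DC than in vehicle in APOE4 hippocampus (84 members, median log2 fold change -0.60, camera adjusted p = 9.16e-07, and adjusted p = 0.00167 with an estimated correlation). The 4 members with the smallest p were Rpl10l, Rps3, Rpl4 and Rps4x; 7 members passed over all genes, and 33 were lower when adjusted over the list alone. The same list had lower values in the DC interaction of that region (median log2 -0.52, adjusted p = 0.000327, and 0.0286 with an estimated correlation), led by Rpl19, Rpl41, Rps24 and Rps4x, of which 0 members passed over all genes or adjusted over the list alone. With the negative probe subtracted both list calls held (adjusted p = 2.46e-08 and 3.31e-06). Without the 13 libraries with a high negative probe, with 2 of 8 DC libraries of 1 run left, neither did (medians -0.083 and -0.13, adjusted p = 0.906 and 0.905).

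Another 7 list calls were lost with an estimated correlation. Oligodendrocyte precursor genes, led by Enpp6, Sox10, Neu4 and Olig2, were lower after DC in APOE4 hippocampus (adjusted p = 0.0412, and adjusted p = 0.110 with an estimated correlation). Ribosomal protein genes were higher in DD than DC in APOE4 hippocampus (adjusted p = 0.00274; 0.0884 estimated), higher in APOE4 than APOE3 vehicle hippocampus (0.0446; 0.429 estimated) and lower in the DD interaction of cortex (0.0166; 0.852 estimated). Glutamate receptor and postsynaptic genes, led by Gria1, Shank2 and Nlgn1, were lower in APOE4 than APOE3 cortex after DC (0.0291; 0.470 estimated). Myelin genes, led by Mal, Fa2h, Mobp and Cnp, were lower in APOE4 than APOE3 hippocampus after DD (0.0395; 0.0729 estimated), and glycolysis genes, led by Aldoa, Pkm, Gapdh and Pdk1, were lower in hippocampus than cortex (0.0306; 0.258 estimated). None of the other lists, among them the microglial, complement, cytokine, interferon, astrocyte, p53, senescence, oxidative phosphorylation and neurotrophic ones, passed in any of the 23 contrasts. Over all treatment contrasts, 14 of 304 list tests had an unadjusted p under 0.05, and list members passed in 21 tests over all genes and in 71 when adjusted over the list alone.

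The genotype comparisons asked which genes differ between APOE4 and APOE3 mice under the same treatment. Lrr1 was lower in APOE4 in cortex with vehicle, DD and DC alike, by 2.29-, 2.79- and 3.07-fold (log2 -1.20, -1.48 and -1.62, SE 0.16 each, edgeR adjusted p = 1.85e-08, 4.13e-12 and 2.67e-13, 8 of 8 libraries each). Its share of the tested counts in vehicle cortex was 5.24% ± 1.67 (SD, n = 8) in APOE3 and 2.59% ± 0.399 (SD, n = 8) in APOE4. Chic2 was 1.70-fold lower in APOE4 after DD and 2.17-fold lower after DC (adjusted p = 9.32e-05 and 6.24e-08, 8 of 8 libraries each). Rgs19, a regulator of G protein signalling, was 2.73-, 2.94- and 3.37-fold higher in APOE4 with vehicle, DD and DC (log2 1.45, 1.55 and 1.75, SE 0.33, 0.27 and 0.37, adjusted p = 0.000994, 9.68e-06 and 0.000209, 8 of 8 libraries each). Over all cortex libraries Rgs19 lay at a median of only 2.78 times the negative probe, with a mean count of 9.29 per library. In hippocampus Rgs19 did not pass the low-count filter. Elof1 was 3.40-fold higher with vehicle and 2.32-fold higher with DD (log2 1.77 and 1.21, SE 0.37 and 0.28, adjusted p = 0.000275 and 0.000450, 8 of 8 libraries each), from 2.88 counts per library in APOE3 vehicle cortex. In mm10, Lrr1 lies on chromosome 12 at 69168814 to 69179012, Chic2 on chromosome 5 at 75005004 to 75044641 and Rgs19 on chromosome 2 at 181688419 to 181694537.

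Further genes higher in APOE4 cortex were Cyp2d12, Inhbb, the activin beta subunit, Pcsk1, a prohormone convertase, and Olfr655, each with vehicle and with DD, 1.53- to 2.38-fold. Coa5 was 1.58-fold higher with DD and 1.46-fold higher with DC. With vehicle, Gm46840 was also 1.59-fold higher, and Mtch2, Ripply2 and Cd99 were 1.53-, 1.52- and 1.39-fold lower. With DD, Nemp2, Eri3, an exoribonuclease, and Tmem65 were 1.61-, 1.64- and 1.68-fold higher. With DC, Xrn1, Gm34733, Lig1, a DNA ligase, 1110065P20Rik and Tysnd1 were 1.56-, 1.55-, 1.53-, 1.40- and 1.40-fold higher. Ptms, Gm9758, Ubb, a ubiquitin gene, Pcbd2 and Rrp36, a factor of ribosomal RNA processing, were 2.01-, 1.79-, 1.74-, 1.58- and 1.38-fold lower. In cortex 12, 12 and 14 genes passed with vehicle, DD and DC, and each was on its side of the APOE3 mean in 7 or 8 of 8 APOE4 libraries. A call with 1 treatment and not another does not show that the genotype difference depends on treatment; the interaction tests are given further on.

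In hippocampus, Lrr1 was again lower in APOE4 with vehicle, DD and DC, by 2.20-, 3.18- and 3.71-fold (log2 -1.14, -1.67 and -1.89, SE 0.16 each, adjusted p = 1.00e-07, 6.40e-13 and 1.41e-14, 8 of 8 libraries each). Chic2 was lower in all 3 as well, by 1.71-, 1.95- and 2.11-fold (adjusted p = 0.00138, 0.000113 and 1.99e-05, in 7, 8 and 8 of 8 libraries). Inhbb and Elof1 were higher with vehicle (1.95- and 2.52-fold) and with DC (1.69- and 2.82-fold), and Gm10265 and Gm52523 were lower in both, by 1.37- and 1.33-fold with vehicle and 1.79- and 1.77-fold with DC. Cyp2d12 was 3.85-fold higher with vehicle (log2 1.94, SE 0.41, adjusted p = 0.000210, 8 of 8 libraries), from a mean count of 1.63 per library in APOE3. Gm46840 was 1.47-fold higher with vehicle, and Mtch2, Pcbd2, Cd99, Ripply2 and Erlin2 were 1.80-, 1.73-, 1.64-, 1.55- and 1.36-fold lower. Under upper-quartile scaling, which moved the median of the tested genes by log2 0.40 in this contrast, all 6 higher calls with vehicle were kept but 1 of the 9 lower ones, Lrr1. Mplkip was 9.84-fold higher with vehicle (log2 3.30, SE 0.65, adjusted p = 0.000114, 8 of 8 libraries); without APOE4 vehicle hippocampus 3, its log2 fold change was 0.99, still past the threshold, while Pcbd2 lost its call (log2 -0.64). With DD, Coa5 was 1.67-fold higher, and with DC, Txlnb was 2.35-fold and Marcks, a substrate of protein kinase C, 1.81-fold higher. In hippocampus 15, 3 and 8 genes passed with vehicle, DD and DC.

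Genotype was fully confounded with the collection plate, so genotype and plate cannot be told apart in any of these 64 calls (36 higher, 28 lower, 33 genes). The negative probe was higher in APOE4 in all 6 contrasts, 1.77- to 8.92-fold (exact p over runs 0.0286, the smallest possible, in 4 of them, 0.171 with DD and 0.0857 with DC in cortex), and p-values over regions not tied to animals are too small where regions share one. With counts summed over runs of wells, 23 of the 36 higher and 21 of the 28 lower calls were kept. With the run as a random block 23 and 25 were kept. The balance of directions moved with the scaling, from 36 higher and 28 lower to 25 and 33 with DESeq2 and 41 and 18 with upper-quartile scaling.

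**Figure D4:**
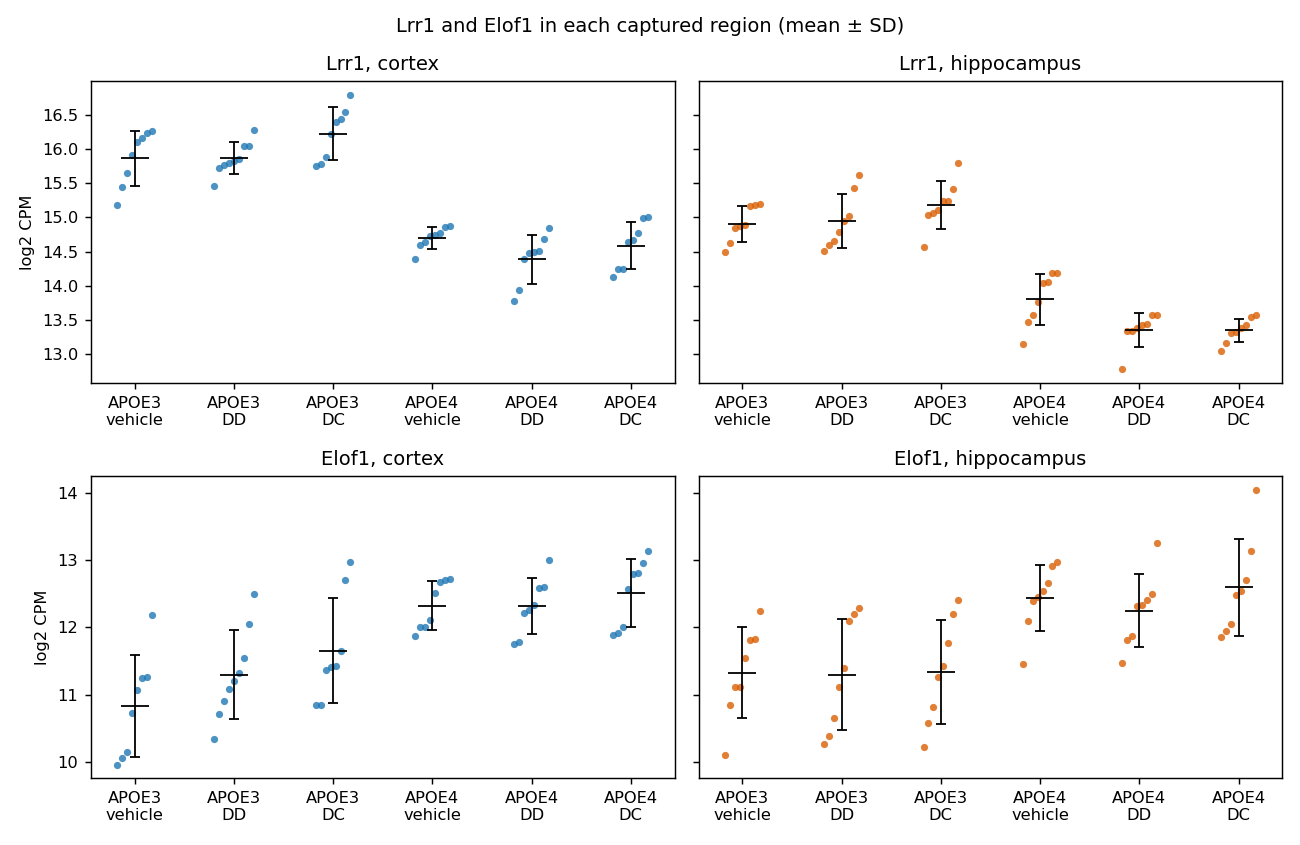
Log2 CPM of Lrr1 and Elof1 in each library by group and region, with group means and SD bars. Lrr1 was 2.29-fold lower and Elof1 3.40-fold higher in APOE4 than in APOE3 vehicle cortex.

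The interaction contrasts asked whether a regimen's effect differs between genotypes, and a plate effect that adds equally on the log2 scale drops out of them. Background counts that differ between the plates do not drop out, since they shrink the log2 fold changes of low-count genes. A background that differs by treatment on 1 plate does not either: after DC the negative probe in hippocampus was 5.16-fold that of vehicle in APOE4 and 1.025-fold in APOE3. In cortex, the DC effect on Chic2 was lower in APOE4 than in APOE3 (log2 difference -0.80, SE 0.23, edgeR adjusted p = 0.0236) and that on Cd99 was higher (0.70, SE 0.20, adjusted p = 0.0236). Chic2 in APOE3 cortex stood at log2 CPM 15.39 ± 0.30 (SD, n = 8) with vehicle and 15.75 ± 0.34 (SD, n = 8) with DC, and in APOE4 at 15.06 ± 0.39 (SD, n = 8) and 14.62 ± 0.38 (SD, n = 8). In hippocampus, the DC effect on Txlnb was higher in APOE4 (log2 difference 1.20, SE 0.33, adjusted p = 0.0245) and that on Lrr1 lower (-0.76, SE 0.22, adjusted p = 0.0271). Txlnb fell in APOE3 from 0.53% ± 0.214 (SD, n = 8) of the tested counts to 0.312% ± 0.200 (SD, n = 8), and stood in APOE4 at 0.749% ± 0.123 (SD, n = 8) and 1.02% ± 0.341 (SD, n = 8).

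For DD, edgeR found 0 interaction genes in cortex and 0 in hippocampus, with 1 and 7 genes at an unadjusted p under 0.05 and 0 by DESeq2 in both. The smallest p among named genes in cortex were those of Chic2 (log2 -0.45, SE 0.22), Gm46840, Lat, Calm2 and Hmga2 on the lower side, and of Fdx2, Cd99, Gm40755, Tmem65 and 2610528J11Rik on the higher side (adjusted p = 0.719 for all 10). In hippocampus they were those of Cyp2d12 (log2 -1.61, SE 0.55, adjusted p = 0.185), Inhbb, Mplkip and Lrr1, and of Coa5, Gm34733, Sprn, Erlin2 and Gm52523. All 4 DC interaction calls ended with counts summed over runs (0 in cortex, 0 in hippocampus), and with the run as a random block 0 and 1 genes passed. With the negative probe subtracted both hippocampus calls ended. Without the 7 libraries with many genes raised in 1 library alone, both cortex calls ended. P-values over regions not tied to animals are too small where regions share one.

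The regimens were compared directly to ask whether docetaxel or cyclophosphamide beside doxorubicin makes a difference. In APOE4 hippocampus, Gm10265 and Gm52523 were higher after DD than after DC, 1.53-fold (log2 0.61, SE 0.14, edgeR adjusted p = 0.00148) and 1.44-fold (log2 0.53, SE 0.10, adjusted p = 0.000210), each in 8 of 8 libraries. Fam177a and Inhbb were lower after DD, 1.75-fold (log2 -0.81, SE 0.23, adjusted p = 0.0130) and 1.52-fold (log2 -0.60, SE 0.18, adjusted p = 0.0166), each in 8 of 8 libraries. Without the 13 libraries with a high negative probe, which leaves 2 of the 8 DC libraries, both of 1 run, 0 of these 4 calls remained. Gm10265 and Gm52523 stood at log2 0.63 and 0.44, and Fam177a and Inhbb turned to 0.35 and 0.09. With all libraries, 0 genes passed with the covariate. Summing runs of wells kept 4 of the 4 calls, and with the run as a random block 2 genes passed.

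In the other 3 comparisons of DD with DC, edgeR found 0 genes: in APOE3 cortex with 12 at an unadjusted p under 0.05 and 1 by DESeq2, in APOE4 cortex with 0 and 0, and in APOE3 hippocampus with 2 and 0. In APOE3 cortex the smallest p were those of Eri3 (log2 -0.88, SE 0.29, adjusted p = 0.167), Elof1, Inhbb, Ptms and Lrr1 on the lower side, and of Mplkip (log2 1.42, SE 0.53, adjusted p = 0.167), Cd99, Gm34733, 1110065P20Rik and Tysnd1 on the higher side. In APOE4 cortex they were those of Actb, Ccl27a, Zfp180, Lrr1 and Elof1, and of Rgs19, Inhbb, Vmn1r189, Eri3 and Coa5 (adjusted p = 0.990 for all 10). In APOE3 hippocampus they were those of Tmed2 (log2 -0.67, SE 0.25, adjusted p = 0.175), Gimap4, Pcbd2, Lrr1 and Fam177a, and of Txlnb (log2 0.88, SE 0.29, adjusted p = 0.129), Marcks, Mtch2, Gm34733 and Gm33888. The regions were not tied to animals here either, and p-values over them are too small where regions share one.

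Apoe, Gfap, Aif1, Cdkn1a, Bdnf and Mbp, markers of lipid transport, astrocytes, microglia, the p53 response, neurotrophic signalling and myelin, lay at the level of the negative probe. Their medians were 0.885, 0.944, 0.892, 0.896, 0.746 and 0.923 times the negative probe in cortex, and 0.870, 0.923, 0.860, 0.948, 0.790 and 0.891 times in hippocampus. None passed the low-count filter, and in fits without it the smallest adjusted p over 138 tests was 0.520 by edgeR, with 1 unadjusted p under 0.05. The panel's Apoe probe was designed for mouse, and the mice carry the human gene.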

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

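All tests of explanations in this part, with the subtraction of the negative probe, its use as a covariate and the removal of libraries with high background, were chosen after the results were seen. Samples far from the others of their group were found by the gap to the nearest sample, a test that chance passes in about 1 in 20 groups of normally distributed values. Total counts and negative probe values were tested without logs, where they are skewed, so that rate need not hold for them. In all, 7 of 36 library measures and 35 of 486 gene levels passed the test, the latter in 29 libraries.

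Mtch2 was lower after treatment in APOE3 and APOE4 cortex and in APOE3 hippocampus. In cortex, the 3 calls (DD and DC in APOE3 and DD in APOE4) were kept after subtraction (log2 -0.86, -1.12 and -0.71). They were kept with the covariate too (-0.88, -1.28 and -0.74). Mtch2 lay at a median of 358 times the negative probe there, so subtraction could hardly move it and cannot decide on background. Over all alternatives the calls were made in 12, 16 and 9 of 16. Their adjusted p ran from 3.03e-05 to 0.983, 7.26e-11 to 0.0306 and 0.00595 to 0.595. In APOE3 hippocampus after DC, the value moved from log2 -1.11 (SE 0.28) to -1.10 (SE 0.24) after subtraction. With the covariate it was -0.58 (SE 0.28, edgeR adjusted p = 0.165), and the call ended. The covariate divides by the tested-gene count, which was 0.375-fold that of vehicle and largely Mtch2 itself. The negative probe was 1.025-fold that of vehicle, but in both groups it lay near the lowest value of 1, where this ratio says little. The covariate therefore cannot decide whether this shrinkage reflects background. Over the alternatives the adjusted p ran from 5.73e-05 to 0.165, and background and treatment cannot be told apart there. Neighbouring regions of 1 animal that move together also stay open, since the labels tie no region to an animal: over 4 runs of wells against 4, without the single-library run of APOE3 DD cortex, the exact p was 0.0286, the smallest possible, in 2 of the 3 cortex contrasts (0.0857 for DC in APOE3) and in 1 of 1 in hippocampus. A response of this mitochondrial gene to chemotherapy is a biological hypothesis that stays open and untested.

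Genes higher or lower in APOE4 than in APOE3 were found in both regions. After subtraction 27 of the 36 higher calls were kept, at a median of 4.38 times the negative probe, but this cannot decide on background. The lowest value in the files is 1, and the median negative probe of APOE3 libraries was 1.27, next to it. Subtraction may thus take too much from low APOE3 counts, which would raise these changes. Their median went from log2 0.79 to 0.84. Of the lower calls 26 of 28 were kept after subtraction, but at a median of 22.7 times, where subtraction can change little. All 64 kept their sign. The 9 higher calls that ended went from a median log2 of 0.71 (SE 0.25) to 0.75 (SE 0.34), through a wider error, and the 2 lower ones from -0.61 (SE 0.22) to -0.53 (SE 0.24). The plate cannot be told apart from the genotype, since 0 genotypes were found on both plates. An effect of the APOE allele is a biological hypothesis that stays open and untested.

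After DC, 8 genes were called in hippocampus of each genotype, where the negative probe was 5.16-fold higher (APOE4; exact p over runs of wells 0.114) or the tested-gene count 0.375-fold that of vehicle (APOE3). In APOE3, the median of the 4 lower genes went from log2 -0.93 (SE 0.25) to -0.94 (SE 0.24) after subtraction and -0.53 (SE 0.27) with the covariate, and that of the 4 higher genes from 0.99 (SE 0.33) to 1.03 (SE 0.45) and 0.75 (SE 0.33). In APOE4, the lower genes went from -0.57 (SE 0.20) to -0.37 (SE 0.19) and -0.38 (SE 0.21), and the higher genes from 0.75 (SE 0.26) to 0.55 (SE 0.38) and 0.18 (SE 0.29). Subtraction kept 3 lower and 0 higher calls in APOE3 and 1 and 0 in APOE4, the latter Mplkip, which rests on APOE4 vehicle hippocampus 3. The covariate kept 1 and 0 in APOE3 and 0 and 0 in APOE4, with smaller changes or wider errors. Background and an effect of DC cannot be told apart for any of these 4 sets, and the biological explanation was not tested.

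Several libraries stood apart in depth or background on the raw scale, without logs. The total count was 46285 and the negative probe 1.86 in APOE3 DC hippocampus 8, 1850582 and 93.1 in APOE4 DC hippocampus 8, and 92106 and 4.10 in APOE4 vehicle hippocampus 8. Mtch2 held 73.0% of the tested counts in APOE3 vehicle hippocampus 5 (2207 of 3022 counts, exact 95% binomial interval 71.4 to 74.6, which covers counting error alone).

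Gene levels (log2 CPM) far from the others of their group were found in cortex as follows. In APOE3 vehicle cortex, Fdx2 stood at 12.70 in library 6 and Hmga2 at 12.80 in library 2. In APOE3 DD cortex, Erlin2 stood at 12.70 in library 6, Mplkip at 15.35 in library 2, and Ripply2 at 11.08 and Txlnb at 10.01 in library 3. In APOE3 DC cortex, Gm52523 stood at 15.76 in library 8. In APOE4 vehicle cortex, Calm2 stood at 10.96 in library 2, Gimap4 at 9.79 in library 7, and Gm46840 at 16.49, Ptms at 12.14 and Vmn1r189 at 12.22 in library 4. In APOE4 DD cortex, Gm33888 stood at 14.85 and Vmn1r189 at 12.16 in library 7, Rrp36 at 13.14 in library 6 and Ubb at 10.57 in library 4. In APOE4 DC cortex, Eri3 stood at 10.38 in library 4, Gm9758 at 9.88 in library 2 and Txlnb at 11.16 in library 1.

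In hippocampus, APOE3 vehicle library 5 stood apart in Gm33888 at 17.25 and Mtch2 at 20.75. In APOE3 DD, Fam177a stood at 10.26 in library 1, Gm40755 at 10.65 in library 7, and Mplkip at 10.38 and Xrn1 at 13.45 in library 5. In APOE3 DC, Gm46840 stood at 15.55 in library 6 and Xrn1 at 14.93 in library 8. In APOE4 vehicle, Gm34733 stood at 13.55 in library 7, Gm40755 at 10.53 in library 2, Gm52523 at 13.99 in library 5 and Mplkip at 16.82 in library 3. In APOE4 DD, Fdx2 stood at 11.65 in library 2, Lrr1 at 12.78 in library 1 and Rrp36 at 12.94 in library 7. In APOE4 DC, Tmed2 stood at 11.94 in library 4.

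In cortex, the effect of DC passed the test of the interaction with genotype for Chic2 (log2 -0.80) and Cd99 (0.70). In hippocampus, Txlnb (1.20) and Lrr1 (-0.76) passed it. With counts summed over runs of wells 0 of these 4 calls were kept. With the run as a random block 0 of 2 were kept in cortex and 1 of 2 in hippocampus. With the negative probe subtracted, neither hippocampus call was kept. The negative probe, which is not a gene, had higher values than in vehicle libraries after DD (1.41-fold) and DC (1.36-fold) in APOE3 cortex and after DC in APOE4 hippocampus (5.16-fold), by exact tests over libraries; over runs of wells the exact p was 0.114, 0.171 and 0.114.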

How the results depend on the processing

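The alternatives that use the negative probe, leave out named libraries or filter at 5 times the negative probe were chosen after seeing the data; the others were not. Of the 23 contrasts, the number of genes stayed within 1.5 times the reported one in 18 with upper-quartile scaling, 19 with DESeq2, 4 without the low-count filter, 13 with summed runs, 13 with the random block, 19 with the fixed block and 19 with only the groups of the contrast. Among the 136 calls, 106 were shared with upper-quartile scaling, 118 with DESeq2, 88 with summed runs, 90 with the random block and 10 without the filter. Upper-quartile scaling moved the median of the tested genes by over 0.1 (log2) in 13 of 23 contrasts (-0.35 to 0.40), and DESeq2 in 2 (-0.10 to 0.06). The low-count filter left 57 and 38 genes to test, and the deepest library, APOE4 DC hippocampus 8, had the smallest share of genes above 2 times the negative probe (0.0651%). Simulated changes of 1.5-fold were called in 34.2% and 55% of genes in APOE3 and APOE4 cortex and in 35.4% and 55% in hippocampus. A filter at the mean and 2 SD of the negative probes was not run, since they come as 1 combined value, and libraries against their region label were not left out, since the marker score was void. Except where fewer genes or samples are named as the difference, the cause was not tested.

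With DESeq2 the numbers of genes were 4 for DC in APOE4 cortex, 7 for genotype with DD in cortex, 1 for DD against DC in APOE3 cortex and 4 for the DC interaction in hippocampus, and Mplkip after DC in APOE4 hippocampus was reversed at 0.41. With upper-quartile scaling they were 0 for DD and 3 for DC in APOE4 cortex, 7 for genotype with DD and 1 for the DC interaction in cortex, and 0 for DD in APOE3 hippocampus.

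Without the low-count filter, where all 19962 genes were tested, the numbers in cortex were 6 for DD in APOE3, 13 for DD and 16 for DC in APOE4, 6 and 7 for genotype with vehicle and DC, 0 for the DC interaction, and 6 and 26 for DD against DC in APOE3 and APOE4. In hippocampus they were 0 for DD and 1 for DC in APOE3, 68 for DD and 186 for DC in APOE4, 32, 0 and 4 for genotype with vehicle, DD and DC, 0 for the DC interaction, and 1 and 70 for DD against DC in APOE3 and APOE4, with 6 for hippocampus against cortex. Reversed values in cortex were Rrp36 0.18 for genotype with DC, Cd99 -0.12, Gm40755 -0.056 and 2610528J11Rik -0.12 for the DD interaction, and Lrr1 0.32 for DD against DC in APOE3. In hippocampus they were Tmed2 -0.19 for DC in APOE3, Fam177a -1.02, Pcbd2 -0.47, Etd -0.53 and Olfr655 -0.67 for DC in APOE4, and Lrr1 0.060 for the DD interaction. For DD against DC they were Gimap4 0.087, Pcbd2 0.080, Lrr1 0.44 and Fam177a 0.27 in APOE3 and Fam177a 1.10 and Inhbb 1.03 in APOE4 hippocampus. Of the 460 genes called without the filter in the contrasts within a region, 246 (53.5%) had over 0.5 of their counts in 1 library. Without the 13 libraries with a high negative probe, the unfiltered numbers in APOE4 hippocampus went from 186 to 8 for DC and from 70 to 9 for DD against DC, with 2 DC libraries of 1 run left.

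Without the filter and without the 7 libraries with many genes raised in 1 library alone, the numbers in cortex were 11 for DD and 18 for DC in APOE4, 6, 5 and 7 for genotype with vehicle, DD and DC, 0 for the DC interaction, and 4 and 22 for DD against DC in APOE3 and APOE4. In hippocampus they were 0 for DD and 1 for DC in APOE3, 5 for DD and 40 for DC in APOE4, 2, 0 and 3 for genotype with vehicle, DD and DC, 0 for the DC interaction, 1 and 92 for DD against DC in APOE3 and APOE4, and 8 for hippocampus against cortex. With the filter and without those 7 libraries they were 0 for DD and 0 for DC in APOE4 cortex, 0 for the DC interaction in cortex, 13 for DC in APOE4 hippocampus and 1 for the DC interaction there, with Mplkip reversed after DC at 0.79. Without APOE4 vehicle hippocampus 3 alone, Mplkip after DC was reversed at 0.40, and the other numbers of genes stayed within 1.5 times.

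With counts summed over runs of wells, which leaves 4 samples per group (5 in APOE3 DD cortex, 1 of them a single library), the numbers were 0 for DD in APOE3 and APOE4 cortex, 0 for DC in APOE4 cortex, 7 and 9 for genotype with DD and DC in cortex, 0 for the DC interaction in cortex, 0 for DD in APOE3 hippocampus, 1 for DD and 1 for DC in APOE4 hippocampus and 0 for the DC interaction there. Gene lists past the threshold were 3 for DD against DC and 0 for hippocampus against cortex. With the run of wells as a random block, the numbers were 0 for DD and 0 for DC in APOE4 cortex, 6 and 7 for genotype with vehicle and DD in cortex, 0 for the DC interaction in cortex, 0 for DD and 0 for DC in APOE4 hippocampus, 1 for the DC interaction in hippocampus, and 1 and 2 for DD against DC in APOE3 and APOE4 hippocampus. With the order of the run as a fixed block they were 4 for DC in APOE4 cortex, and in hippocampus 4 for DD and 13 for DC in APOE4 and 4 for the DC interaction. With only the groups of the contrast in the fit, so fewer samples, they were 4 for DC in APOE4 cortex, and in hippocampus 4 for DD in APOE3, 0 for DC in APOE4 and 0 for the DC interaction.

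With the negative probe subtracted, the numbers in hippocampus were 3 for DD and 3 for DC in APOE3, 3 for DC in APOE4, 0 for the DC interaction and 1 for DD against DC in APOE4, with Fam177a after DC in APOE4 reversed at -0.036; lists were 1 for genotype and 0 for hippocampus against cortex. With the covariate they were 2 for DC in APOE4 cortex, and in hippocampus 1 for DC in APOE3, 0 for DC in APOE4, 5 for genotype with DC and 0 for DD against DC in APOE4, with Fam177a after DC in APOE4 reversed at -0.047 and Gm33888 for DD against DC in APOE3 at -0.0498. Without the 13 libraries with a high negative probe, which leaves 4 of 8 APOE4 DC libraries in cortex and 2 of 8, of 1 run, in hippocampus, they were 9 for DC in APOE4 cortex and 1 for the DC interaction in cortex, and in hippocampus 4 for DD in APOE3, 6 for DD and 0 for DC in APOE4, 4 for genotype with DC, 4 for the DC interaction and 0 for DD against DC in APOE4. Reversed values there were Zfp180 0.031 for DD against DC in APOE4 cortex, Fam177a -0.57 for DC in APOE4 hippocampus, and Fam177a 0.35 and Inhbb 0.093 for DD against DC in APOE4 hippocampus; lists were 1 for treatment, 1 for the interaction and 0 for DD against DC. With genes at 5 or more times the negative probe, so fewer genes, the numbers in cortex were 5 for DC in APOE4, 6, 3 and 9 for genotype with vehicle, DD and DC and 1 for the DC interaction, and in hippocampus 3 for DD in APOE3, 1 for DC in APOE4, 5 for genotype with DC, 1 for the DC interaction and 1 for DD against DC in APOE4.

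With an estimated correlation, lists past the threshold were 1 for treatment, 0 for genotype, 1 for the interaction, 0 for DD against DC and 0 for hippocampus against cortex. With vehicle libraries split, so fewer samples in each contrast, the lowest overlap of DD and DC was 0 in APOE3 and APOE4 cortex and 0 in APOE3 and APOE4 hippocampus. The highest was 0 in APOE4 cortex, APOE3 hippocampus and APOE4 hippocampus.

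Leaving out the runs of each order in turn gave these ranges. In cortex they were 0 to 3 for DD and 3 to 7 for DC in APOE3, 0 to 7 for DD and 0 to 6 for DC in APOE4, 5 to 16, 6 to 13 and 9 to 13 for genotype with vehicle, DD and DC, 0 to 0 and 0 to 3 for the DD and DC interactions, and 0 to 2 and 0 to 0 for DD against DC in APOE3 and APOE4. In hippocampus they were 0 to 2 for DD and 3 to 6 for DC in APOE3, 1 to 4 for DD and 1 to 10 for DC in APOE4, 10 to 12, 2 to 3 and 5 to 9 for genotype with vehicle, DD and DC, 0 to 0 and 0 to 1 for the DD and DC interactions, and 0 to 1 and 2 to 16 for DD against DC in APOE3 and APOE4. They were 25 to 28 for hippocampus against cortex, and Mplkip after DC in APOE4 hippocampus ran from -2.53 to 0.63, reversed without the second runs. The DD calls in APOE3 cortex ended (0 genes) without the second or the third runs.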

Other observations

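The comparison of genes between regions and treatments described first, and the splits of the samples after it, were tested after the results were seen. Of the 8 genes called lower in cortex after DD or DC in either genotype, 6 were among the 14 that were higher in vehicle hippocampus, out of 37 genes in both tests; both comparisons use the same vehicle cortex libraries, so no test of this overlap is given. Mtch2, a mitochondrial outer membrane protein, and Ripply2, a transcriptional corepressor, were among them. After DD, 9 of the 13 genes higher in hippocampus that were tested without Mtch2 had negative values in APOE3 cortex (median log2 -0.097) and 11 of 13 in APOE4 cortex (median -0.11). After DC, 10 of the 13 had negative values in APOE3 cortex (median log2 -0.31) and 11 of 13 in APOE4 cortex (median -0.28). Of the 14 genes lower in hippocampus, 8 and 6 had negative values in APOE3 and APOE4 cortex after DD, and 5 and 5 after DC. With Mtch2 left out of the fit, 5 of the 9 lower cortex calls of other genes were kept, 1 of 1 after DD and 4 of 4 after DC in APOE3, and 0 of 4 after DD in APOE4. Libraries of a run of wells were correlated at 0.247 in cortex and 0.151 in hippocampus.

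Chance was examined with splits of the samples into groups of the same sizes, 100 per contrast with the real one included. In APOE3 cortex, 3 of 100 splits gave as many genes as DD (2 genes, highest other 3) and 1 of 100 as many as DC (7, highest other 6). In APOE4 cortex, 1 of 100 gave as many as DD (7, highest other 2) and 13 of 100 as many as DC (1, highest other 4). In hippocampus, 3 of 100 gave as many as DD (1, highest other 1) and 1 of 100 as many as DC (8, highest other 3) in APOE3, and 5 of 100 as many as DD (2, highest other 3) and 4 of 100 as many as DC (8, highest other 13) in APOE4. Splits that kept each run of wells whole, 35 per contrast and without the single-library run of APOE3 DD cortex, gave as many genes in 3 for DD and 1 for DC in APOE3 cortex, in 1 for DD and 11 for DC in APOE4 cortex, in 7 for DD and 1 for DC in APOE3 hippocampus, and in 8 for DD and 2 for DC (highest other 10) in APOE4 hippocampus. Both kinds of split had a share under 0.05 for DC in APOE3 cortex and hippocampus and DD in APOE4 cortex, and not for the other 5. That share of 1 of 35 is the smallest these splits can give, without adjustment over contrasts. Runs are not tied to animals, so chance at the level of animals is not excluded. In DD in APOE4 cortex, however, 0 of the 7 calls were kept with counts summed over runs, with the run as a random block, or under upper-quartile scaling.

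For APOE4 against APOE3 in cortex, 1 of 100 splits gave as many genes with vehicle (12, highest other 5), with DD (12, highest other 6) and with DC (14, highest other 9). In hippocampus, 1 of 100 gave as many with vehicle (15, highest other 3), with DD (3, highest other 2) and with DC (8, highest other 6). With runs kept whole, 1 of 35 gave as many with vehicle, DD (13 genes without the single-library run) and DC in cortex and with vehicle in hippocampus, 2 of 35 with DD (highest other 3) and 3 of 35 with DC (highest other 11) in hippocampus. Both kinds of split had a share under 0.05 in 4 of these 6, which does not exclude chance at the level of animals, and the plate was excluded in 0. For hippocampus against cortex, 1 of 100 gave as many (28, highest other 19).

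For the DC interaction, 2 of 100 splits gave as many genes in cortex (2, highest other 3) and 4 of 100 in hippocampus (2, highest other 6). The hippocampus value, 3 times the real one, points to a structure of the samples, but what those splits share was not tested. For the DD interaction, 100 of 100 gave as many as the 0 genes of cortex (highest other 1) and of hippocampus (highest other 2). For DD against DC, 100 of 100 gave as many as the 0 genes of APOE3 cortex (highest other 2), APOE4 cortex (highest other 4) and APOE3 hippocampus (highest other 1), and 4 of 100 as many as the 4 genes of APOE4 hippocampus (highest other 10). With runs kept whole, 4 of 35 did so in APOE4 hippocampus (highest other 10). In all, splits of libraries had a share under 0.05 in 16 of the 23 contrasts; of the 18 with splits of whole runs, 7 had it in both kinds and 6 in splits of libraries alone. For the interactions and hippocampus against cortex, splits of whole runs were not run.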
